A study of Rangifer tarandus with 4 samples.

How the data were processed

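Dermal cells of antler velvet grafted onto the back of reindeer were measured by droplet single-cell RNA sequencing in 4 libraries: 2 from 6 weeks after grafting and 1 each from 3 and 6 months, per the titles of the libraries. The design text of the series gives 4 weeks to the removal of staples just before harvest; the titles were used. Per the labels' protocols, the epidermis was taken off with dispase, the dermis was digested with collagenase, 10000 viable cells were sorted per library, and libraries were made with the 10x 3' chemistry of version 3. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode with no normalization; per the submitters' processing notes they were made with STAR (version not given) and Cell Ranger 3 against a bovine reference, and Seurat was used afterwards. The genome build and annotation are not given in the sources used here. The matrices hold 21880 genes with bovine identifiers, of which 5070 have no symbol; 87 symbols stand on several identifiers.

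The 4 libraries held 13810 barcodes. Cells with over 10% of UMIs in 13 mitochondrial genes or under 300 genes were left out (60 and 81 at 6 weeks, 38 at 3 months, 109 at 6 months), as were 35, 158, 294 and 7 cells with the highest Scrublet scores, and 13028 cells remained. The number marked as doublets follows a rate of 0.8% per 1000 cells; it was set after the automatic threshold had marked 84 cells in all. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were joined over 15 neighbours and clustered by Leiden at resolution 1 with scanpy 1.11.5 (leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15), without integration of libraries. Clusters were named "-like" from marker genes set before the data were examined, with at least 3 markers found in 10% of cells. A class score of at least 0.4 and a share of at least 50% of the markers were required too. Both were set after the clusters were seen. A cluster also stayed unnamed if its 10 leading genes held more markers of another class than of its own. The same held for a cluster with few UMIs per cell and none of its own markers among those genes. Cluster 0 (best class B or plasma) and cluster 21 (best class Schwann) met the score and the share, and stayed unnamed by the rule on leading genes. Clusters without a name held 11.7% ± 0.376 (SD, n = 2) of cells at 6 weeks, 2.10% at 3 months and 4.50% at 6 months.

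Counts were summed per library and class in the 5 classes with at least 20 cells in every library. Each class was tested with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM, robust quasi-likelihood) with time as a factor of 3 levels and a Benjamini-Hochberg adjusted p under 0.05. The 2 libraries of 6 weeks leave 1 residual degree of freedom, and each lone later library is assumed to vary like them. CPM (counts per 1000000 counts) are scaled by the TMM library sizes in tested classes and by all UMIs of the class in others, SE is the fold change over the root of the quasi-F, and both contrasts share the 6-week libraries. On simulated data for fibroblast-like cells (12747 genes) edgeR recovered 50% of 4-fold and 91% of 8-fold changes at 3 months with 12 false calls, and 61% and 94% at 6 months with 31 false calls. The changes were put into 100 genes at each fold, drawn from genes with at least 5 expected counts in the smallest library. Recovery of genes with fewer counts was thus not measured. The share of false calls among all calls was above 0.05 at both times. The spread put into the simulated libraries was the one estimated from the 6-week libraries.

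Named genes follow a rule set before the data were examined: among genes with a usual symbol, at least 50 CPM in the higher group and the later library outside the range of both 6-week libraries, the 12 with the largest rise and the 12 with the largest fall that passed in fibroblast-like cells, and 5 and 5 in other classes. Of the genes chosen by this rule, 1 is not reported here but is counted among the named values. From each of 28 gene lists, also set beforehand, up to 4 members with at least 20 CPM were added. A list's median log2 fold change is set beside its percentile among 10000 random lists matched on expression and beside the difference between the 6-week replicates; it describes these libraries and is no test across animals. Of 126 pairs of a class and a list, those described were chosen after the values were seen. Class shares carry exact Clopper-Pearson 95% intervals.

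The alternatives set before the data were examined numbered 21: DESeq2 1.42.0, its kind of size factors, other filters on low counts, a line on log2 weeks, thinned cells and UMIs (1000 per cell, with shallower cells left out), other clusterings, all barcodes or doublets kept, all cells summed, and each 6-week replicate left out; 3 more were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Ungrafted skin was not used here.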

Results

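Antler velvet is the haired skin that covers a growing antler, and it is renewed each year with the antler. The series moved full-thickness velvet of reindeer onto the animals' own back, a site where skin does not regenerate, to ask whether the regenerative property of velvet stays with the tissue after it is moved. Dermal cells of the grafts were profiled by droplet single-cell RNA sequencing with the 10x 3' chemistry of version 3. There were 2 libraries from 6 weeks after grafting, 1 from 3 months and 1 from 6 months. The comparisons that these libraries allow are 3 months against 6 weeks and 6 months against 6 weeks, which share the 6-week libraries. The labels do not tie libraries to animals, so the spread between both 6-week libraries may be technical. Ungrafted velvet and back skin were not analysed here.

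The 6-week libraries held 2138 and 4519 barcodes with 13048628 and 28554179 counts of unique molecular identifiers (UMIs). The 3-month library held 6103 barcodes with 27350962 UMIs, and the 6-month library held 1050 barcodes with 8872415 UMIs. After cells were filtered, 2043, 4280, 5771 and 934 cells remained in that order, with medians of 5332, 5497, 3659 and 6423 UMIs per cell. Cells fell into 24 clusters, and 8 classes were named from marker genes.

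Fibroblast-like cells were the largest named class at 6 weeks and 3 months, and keratinocyte-like cells at 6 months with the clustering used here. Fibroblast-like cells made up 42.1% ± 7.48 (SD, n = 2) of cells at 6 weeks, 59.7% at 3 months (exact Clopper-Pearson 95% interval 58.4 to 60.9) and 25.7% at 6 months (22.9 to 28.6). Keratinocyte-like cells held 10.4% ± 1.37 (SD, n = 2) at 6 weeks, 3.00% at 3 months (2.57 to 3.47) and 35.3% at 6 months (32.3 to 38.5). Mural-like cells, the contractile cells around vessels, held 9.38% ± 4.38 (SD, n = 2) at 6 weeks, 3.81% at 3 months (3.33 to 4.34) and 2.36% at 6 months (1.48 to 3.54). Lymphatic endothelial-like cells held 0.156% ± 0.0558 (SD, n = 2), 0.347% (0.212 to 0.535) and 4.82% (3.54 to 6.39). Mast-like cells held 3.64% ± 0.303 (SD, n = 2), 5.61% (5.03 to 6.24) and 0.321% (0.0663 to 0.936), the last from 3 cells. Vascular endothelial-like cells held 14.0% ± 5.95 (SD, n = 2), 18.0% (17.0 to 19.0) and 19.0% (16.5 to 21.6). T or NK-like cells held 3.57% and 9.77% in the 6-week libraries, a mean of 6.67% ± 4.38 (SD, n = 2), then 6.74% (6.11 to 7.42) and 6.32% (4.84 to 8.07). Macrophage-like cells held 1.85% ± 0.771 (SD, n = 2), 0.710% (0.510 to 0.963) and 1.71% (0.982 to 2.77). The share of keratinocyte-like cells depends on the clustering: with Leiden resolution 2 it was 4.74%, 0.797% and 18.6% in that order, and fibroblast-like cells (25.7%) were the largest named class at 6 months. No macrophage-like class was named (0% of cells) with Leiden resolution 0.5, with doublets kept or with every barcode kept. With resolution 0.5 the immune classes together still held 192, 639, 754 and 78 cells, and T or NK-like and mast-like cells kept their numbers. As many cells thus took another immune name, and the identity of the class is unsure. With 1 library at each later time no share was tested, and the intervals cover counting error only. Dispase was used to take off the epidermis and cells were sorted on scatter and viability, and both steps can set these shares.

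**Figure D1:**
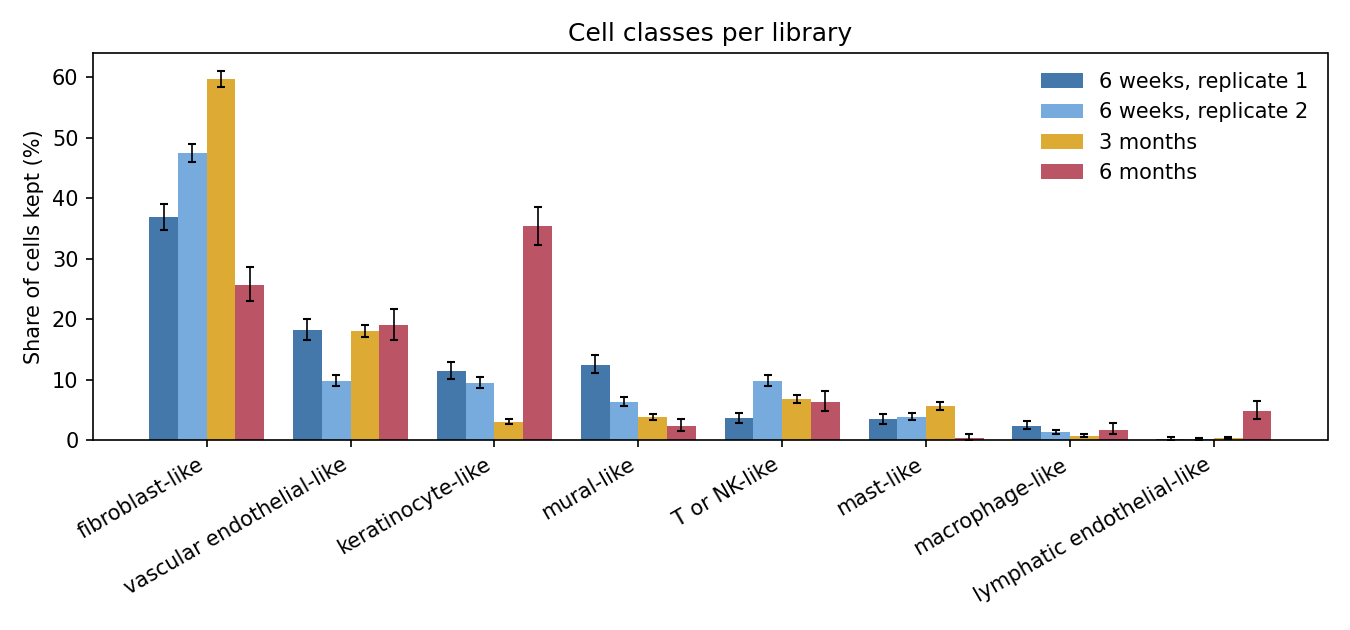
Share of the cells kept in each library (%, vertical axis) that fell into each cell class (horizontal axis), with 1 bar per library and exact 95% Clopper-Pearson intervals as error bars. Fibroblast-like cells stand at 59.7% at 3 months and keratinocyte-like cells at 35.3% at 6 months.

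In fibroblast-like cells at 3 months, the cytokine genes IL6 and IL1A and the prostaglandin gene PTGS2 fell. IL6, which encodes an inflammatory cytokine, stood at 686 ± 329 CPM (SD, n = 2) at 6 weeks and at 7.57 CPM at 3 months, a log2 fold change of -6.50 ± 0.67 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0165). IL1A fell by 3.98 on the log2 scale. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, fell by 3.26 from 440 ± 50.7 CPM (SD, n = 2), and BDKRB2, a bradykinin receptor, fell by 2.70. ANGPTL5 fell by 5.43, ZFAND2A fell by 5.10, CITED4 by 4.31, TMEM100 by 3.53, PTN by 3.34, PHLDA1 by 2.84 and RGS16 by 2.77. The largest rises were those of CDH4, a cadherin, at 5.33 ± 0.32 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00144) from 2.62 to 103 CPM, and of STC1, a secreted glycoprotein, at 5.30 ± 0.65 from 6.44 to 235 CPM. KIT rose by 3.81, DPP4 by 3.74, CDON by 3.19, COL6A5 by 3.16, FAM20A by 3.15, TCAF1 by 2.87, C1QTNF7 by 2.83, TBC1D2B by 2.68, CPXM2 by 2.66 and GLDN by 2.62 on the same scale.

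Among 12747 genes tested in fibroblast-like cells, 580 passed at 3 months by the edgeR quasi-likelihood test, 346 higher and 234 lower. In edgeR the count moved with the scaling: with size factors of the DESeq2 kind in place of TMM, 1 gene passed (1 higher and 0 lower). There 3179 genes had an unadjusted p under 0.05 in edgeR against 3365 with TMM, and the median of all genes moved by -0.11 on the log2 scale. Of the 38 named values that passed at 3 months, 1 passed with those size factors. DESeq2, which uses size factors of that kind, called 511, 113 higher and 398 lower, and all 38 passed there. Both edgeR fits differed in the scaling alone, so within edgeR the calls were lost with the change of scaling. DESeq2 also differs in its test and its estimate of the spread, so its count cannot show how far the calls depend on scaling. A line on log2 weeks over the 4 libraries called 1 gene.

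In fibroblast-like cells at 6 months IL6 was again low, and a steroidogenic gene and an eosinophil chemokine were high. IL6 stood at 6.90 CPM, a log2 fold change of -6.63 ± 0.74 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0276). COL11A1, a fibrillar collagen gene, fell by 3.60 from 777 ± 12.9 CPM (SD, n = 2) to 64.2 CPM, and VCAN, the proteoglycan versican, fell by 2.54. PTGS2 fell by 2.81, NFKBIZ by 2.51, TNFAIP3 by 2.12 and PI16 by 2.78. ANGPTL5 fell by 4.42, TCIM by 3.67, TENM3 by 2.73, RGS16 by 2.36 and TRIB2 by 2.18. STAR, which carries cholesterol into mitochondria for steroid synthesis, rose by 6.40 ± 0.38 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00203) from 1.99 to 155 CPM. THBS4, a thrombospondin, rose by 3.84 from 274 ± 118 CPM (SD, n = 2) to 3909 CPM, and CCL11, the chemokine eotaxin, rose by 3.44 from 50.9 ± 1.25 CPM (SD, n = 2) to 552 CPM. PGGHG rose by 3.80, C1QTNF7 by 3.77, FXYD1 by 3.37, POLE4 by 3.15, KCNE4 by 3.06, FAM20A by 3.06 and MRGPRF by 3.04. The rise of PGGHG was not particular to this class: it rose by 4.45 in keratinocyte-like and 4.64 in T or NK-like cells of the same library. KRT14 and SFN, keratinocyte genes, rose by 4.99 and 4.04 to 228 and 59.4 CPM. KRT14 stood at 44397 CPM in the keratinocyte-like cells of the same library, at 283 CPM in its vascular endothelial-like cells and at 183 CPM in its mural-like cells.

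At 6 months 114 genes passed in fibroblast-like cells by the edgeR quasi-likelihood test, 92 higher and 22 lower; with size factors of the DESeq2 kind 12 passed, 12 higher and 0 lower, and DESeq2 called 192, 110 higher and 82 lower. The 6-month class held 240 cells and 1371877 UMIs, against 18472775 UMIs from 3444 cells at 3 months.

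Lists of genes fixed before the data were examined showed which groups moved in fibroblast-like cells. All 14 measured NF-kB response genes lay below both 6-week libraries at 3 months, and 13 did at 6 months. At 3 months 7 of them fell over all genes tested (12 adjusted over the list alone), with a list median of -2.08 on the log2 scale. At 6 months 3 fell (11 adjusted over the list alone), with a median of -1.83. Both medians ranked at percentile 0 among 10000 random lists matched on expression, and the list differed by 0.58 between replicates 2 and 1 of 6 weeks. With cells thinned to 1 number of UMIs the medians were -1.95 and -1.31. TNFAIP6, a hyaluronan-binding protein gene, fell by 2.64 at 3 months, and RELB, an NF-kB subunit gene, fell by 2.36. NFKBIZ, which fell at 6 months, had a log2 fold change of -1.64 at 3 months (edgeR, Benjamini-Hochberg adjusted p = 0.055). Of 18 measured chemokine and cytokine genes, 3 fell at 3 months (4 adjusted over the list alone; median -2.28) and 2 fell at 6 months (3 adjusted over the list alone; median -1.38), against a difference of 0.77 between the 6-week replicates. That list rests on 6-week replicate 2: without it the medians were -1.51 and -0.14. CXCL3 stood at 2947 ± 1966 CPM (SD, n = 2) at 6 weeks, 157 CPM at 3 months and 300 CPM at 6 months, and did not pass at either time.

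The clusters that held the fibroblast-like cells differed between the times, and most IL6 counts of 6 weeks lay in 1 cluster. IL6 stood at 1322 and 1210 CPM in cluster 4 of the 6-week libraries, which held 20.5% and 45.8% of their fibroblast-like cells, and at 40.9 and 6.88 CPM in cluster 3, which held 41.8% and 17.3%. Cluster 4 held 0.319% of the class at 3 months and 6.67% at 6 months, where IL6 stood at 22.4 CPM (1 count in 11 cells) and 73.6 CPM (9 counts in 16 cells). At 3 months clusters 20 and 6 held 42.9% and 28.0% of the class, and at 6 months clusters 3 and 16 held 46.3% and 28.3%. Inside clusters the NF-kB list did not move alike. At 3 months its median log2 ratio to 6 weeks was 0.16 in cluster 16 (318 cells, against 104 of 6-week replicate 2), 0.063 in cluster 6 (964 cells), -1.02 in cluster 13 (386 cells), -0.76 in cluster 3 (19 cells) and -1.68 in cluster 4 (11 cells). At 6 months it was -0.34 in cluster 3 (111 cells), -1.09 in cluster 16 (68 cells), -2.48 in cluster 4 (16 cells) and 0.58 in cluster 6 (14 cells).

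**Figure D2:**
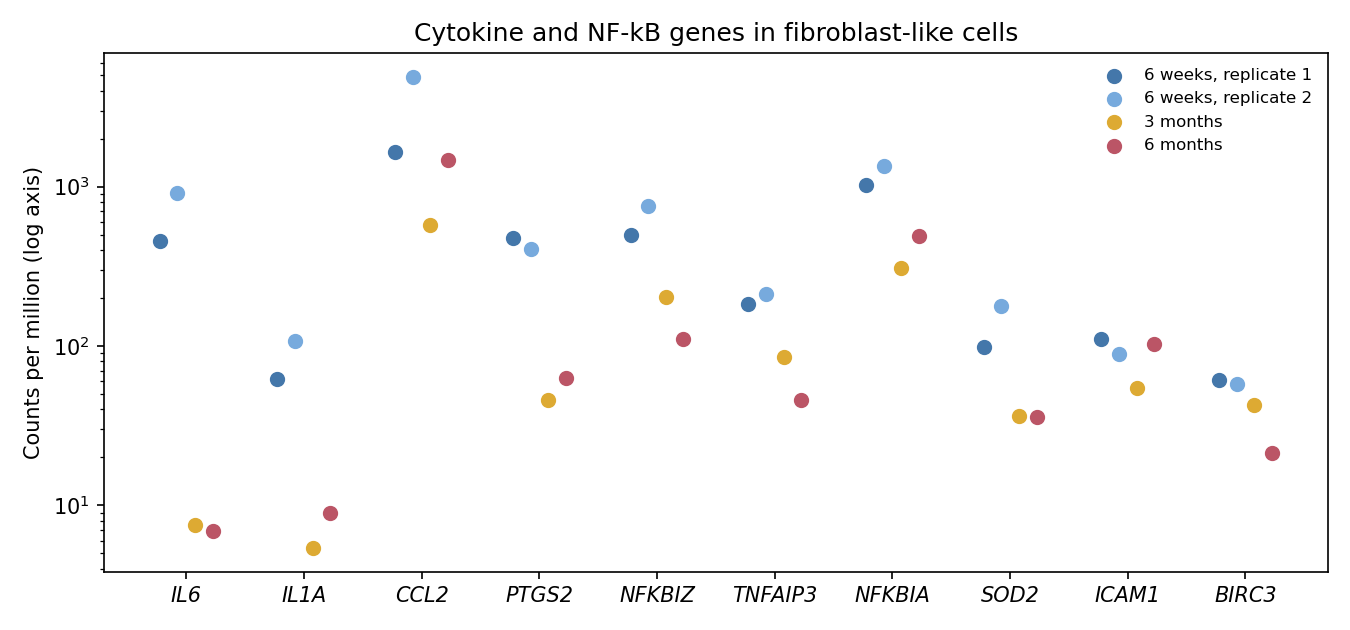
Level of 10 cytokine and NF-kB genes in fibroblast-like cells (CPM, log axis), with 1 point per library. IL6 lies at 453 and 918 CPM at 6 weeks, 7.57 CPM at 3 months and 6.90 CPM at 6 months. CCL2 overlaps more between the times, while ICAM1, as a gene of the NF-kB list, lies below both 6-week libraries at 3 months.

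Matrix genes of fibroblast-like cells moved in both directions. Of 27 measured genes of fibrillar matrix and crosslinking, COL11A1 fell by 2.22 and P4HA3, a prolyl hydroxylase subunit, fell by 1.37 at 3 months, and 25 did not pass (4 rose and 4 fell adjusted over the list alone). The list median was 0.01 at 3 months, where it turned to -0.10 with size factors of the DESeq2 kind and lay at -0.25 and 0.25 without replicate 1 and 2 of 6 weeks, and -0.43 at 6 months, when COL11A1 alone fell (-0.07 without 6-week replicate 2). POSTN, the matricellular protein periostin, stood at 775 ± 347 CPM (SD, n = 2) at 6 weeks and 2316 CPM at 3 months without passing. Of 16 measured proteases and inhibitors, 3 rose and 2 fell at 3 months: MMP19 rose by 2.24 and the collagen-degrading cathepsin gene CTSK rose by 1.62, to 2502 CPM. ADAM12 fell by 1.84 at 6 months. Of 19 elastic fibre and proteoglycan genes 1 rose and 0 fell at 3 months, and 1 rose and 1 fell at 6 months, the latter VCAN, with medians of -0.38 and -0.52, which were -0.06 and 0.74 without 6-week replicate 2. None of 11 basement membrane genes passed over all genes tested in edgeR, while 6 fell at 6 months adjusted over the list alone, with a median of -1.26 at 6 months and -0.31 at 3 months (-0.080 without 6-week replicate 1). COL4A1, a basement membrane collagen gene, stood at 641 ± 312 CPM (SD, n = 2) at 6 weeks and 138 CPM at 6 months.

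None of 12 contractile genes passed at either time in edgeR, with medians of -0.96 at 3 months and -1.94 at 6 months, or -1.49 with 1 gene without counts set at its bound; the 6-month median was -1.18 without 6-week replicate 2. ACTA2, the smooth muscle actin of myofibroblasts, stood at 534 and 160 CPM at 6 weeks, 68.3 CPM at 3 months and 20.7 CPM at 6 months. Adjusted over the list alone, 1 contractile gene fell at 3 months, and 1 rose and 3 fell at 6 months. Of 16 TGF-beta response genes, CCN2, a connective tissue growth factor, fell by 2.09 at 3 months, and 0 passed at 6 months (6 fell and 2 rose, then 4 fell and 2 rose, adjusted over the list alone); the medians were -0.80 and -0.69. Of 15 hypoxia and glycolysis genes, the glucose transporter gene SLC2A1 fell by 2.00, the vascular growth factor gene VEGFA by 1.79 and LDHA by 1.71 at 3 months, with a median of -1.05 (6 fell adjusted over the list alone) that was -0.25 without 6-week replicate 2. None passed at 6 months, where the median was -0.03, or -0.46 and 0.24 without replicate 1 and 2 of 6 weeks.

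Of 13 listed antigen presentation genes 10 were measured in fibroblast-like cells, and BOLA, a class I histocompatibility gene, fell by 1.67 at 3 months. At 6 months the gene stood at 1052 CPM against 312 ± 78.5 CPM (SD, n = 2) at 6 weeks, which did not pass, and the list medians were -0.82 and 0.56, the latter 0.36 without 6-week replicate 2. Of 20 interferon response genes 2 rose and 0 fell at 3 months and 0 passed at 6 months, with medians of -0.29 and 0.90, while replicate 2 of 6 weeks lay at -0.96 relative to replicate 1. The interferon medians were 0.90 and 1.91 without 6-week replicate 1, and -0.84 and 0.46 without replicate 2. IFI6 stood at 339 and 103 CPM in the 6-week libraries, 55.8 CPM at 3 months and 480 CPM at 6 months. Of 12 complement genes 0 passed at either time (2 rose at 6 months adjusted over the list alone), with medians of -0.53 and 0.72 and a replicate difference of 0.76; the medians were 0.63 and 1.34 without 6-week replicate 2, and the 6-month median was 0.29 without replicate 1.

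Genes that mark dermal layers and body position gave few calls. DPP4, a surface peptidase gene, rose by 3.74 at 3 months and 2.67 at 6 months, and PI16 fell by 1.93 and 2.78, out of 12 reticular and adventitial genes with medians of 0.17 and -0.34, which were -0.045 and -0.69 without 6-week replicate 1 and 0.38 and -0.14 without replicate 2. Of 15 papillary and follicle-associated genes 1 fell at 3 months and 0 at 6 months, with medians of -0.41 and -0.53 and a replicate difference of -0.91; the 3-month median was 0.73 without 6-week replicate 1 and -0.072 without replicate 2. ALX1, a homeobox gene of the developing face, fell by 3.73 at 3 months and 2.77 at 6 months from 42.2 ± 8.20 CPM (SD, n = 2). It was the only one of 8 measured cranial regulators to pass, and the list medians were -1.88 (-2.95 without 6-week replicate 2) and -1.46. Without passing, DLX5 had 0 counts at 3 months against 332 at 6 weeks. On a floor of 3 counts that is at least 101-fold lower (26.3-fold without 6-week replicate 2). DLX6 had 0 against 47, at least 15.0-fold lower (6.20-fold without that replicate). None of 9 trunk regulators passed (medians 0.60 and -0.11, with a replicate difference of -0.68; without replicates 1 and 2 in turn the 3-month median was 1.06 and 0.23, and the 6-month median was -0.016 without replicate 2), and none of 18 measured HOX genes did (medians 0.31 and 0.82, with a replicate difference of 0.61; the medians were -0.29 and 0.54 without 6-week replicate 1, and 1.44 and 2.11 without replicate 2). HOXC6 stood at 11.1 ± 3.74 CPM (SD, n = 2) at 6 weeks, 9.76 CPM at 3 months and 20.7 CPM at 6 months. Of 30 growth factor and developmental genes, PTN fell at 3 months and IGF2, a fetal growth factor, rose by 2.32 at 6 months to 474 CPM; the medians were -0.01 and -0.10, and lay at -0.16 to 0.0021 without either 6-week replicate. None of 19 WNT pathway genes passed (medians -0.43 and 0.19, which were 0.28 and 0.37 without 6-week replicate 1 and -0.69 and -0.048 without replicate 2); SFRP2, a secreted WNT modulator, stood at 1350 and 5408 CPM at 6 weeks, 125 CPM at 3 months and 651 CPM at 6 months.

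The list of genes known to respond to tissue dissociation was included as a check of cell handling. In fibroblast-like cells its median was -0.72 at 3 months, at percentile 37.7 of the random lists (-0.47 without 6-week replicate 2), and 0.39 at 6 months, at percentile 100. HSPB1, a small heat shock protein gene, fell by 2.05 at 3 months, and FOS, an immediate early gene, rose by 1.92 at 6 months.

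**Figure D3:**
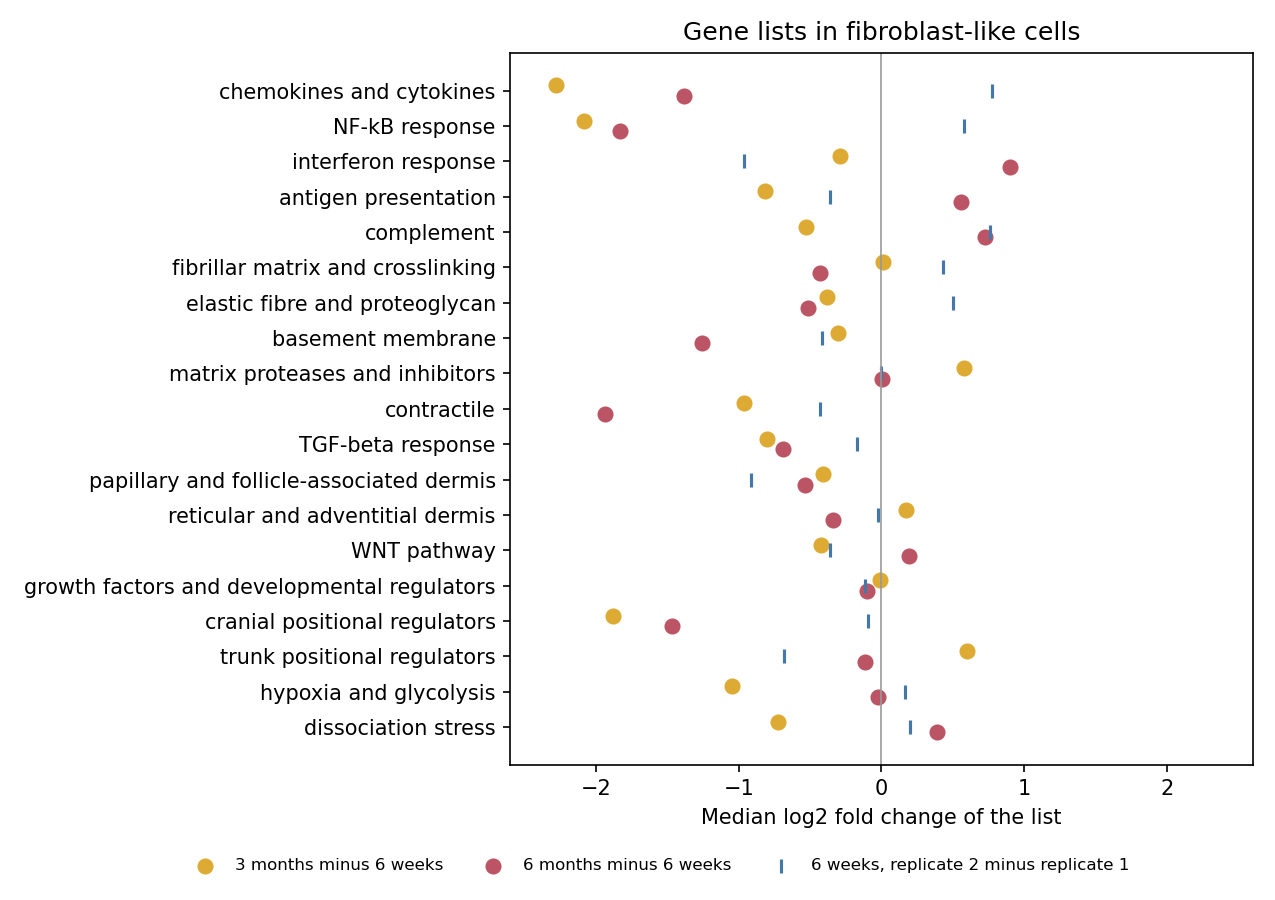
Median log2 fold change of each gene list in fibroblast-like cells (horizontal axis, list names on the vertical axis) at 3 months (yellow) and 6 months (red) against 6 weeks, with the difference between the 6-week replicates as blue ticks. The NF-kB list lies at -2.08 and -1.83 against 0.58 between replicates.

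In keratinocyte-like cells at 3 months, several S100 genes of activated epidermis were nearly without counts. S100A7 had 0 counts at 3 months against 844 ± 410 CPM (SD, n = 2) at 6 weeks, at least 302-fold lower against a floor of 3 counts in the later library (198-fold without 6-week replicate 1). On the same floor S100A8 was at least 145-fold, S100A12 at least 285-fold, CRCT1 at least 126-fold and MMP1 at least 18.9-fold lower, and all of these passed, as did ATP6V1C2, at least 24.1-fold lower. S100A9 had 2 counts at 3 months, a ratio of 6 weeks to 3 months of 421 (95% counting interval 116 to 3478). Of 7 measured wound epidermis genes 4 fell (7 adjusted over the list alone), with a fitted median of -8.71, or -4.24 with genes at 0 set at their bound. The neutrophil chemokine gene CXCL8 fell by 7.04 and CXCL2 by 3.96, and of 12 chemokine and cytokine genes 3 rose and 6 fell. LGR5, a hair follicle stem cell receptor, rose by 3.04 to 139 CPM, the complement gene C3 by 4.86, WFDC3 by 2.77 and TXNIP by 2.61. WNT16 rose from 10.4 to 171 CPM, but its log2 fold change was -1.48 with Leiden resolution 2. The keratinocyte-like class leaves out the unnamed cluster 12, led by the hair keratin genes KRT35 and KRT85. That cluster held 124 and 205 cells at 6 weeks, 25 at 3 months and 10 at 6 months, so hair follicle values here do not cover it. Of 10 hair follicle genes 3 rose and 1 fell (median 0.93, or 0.025 with Leiden resolution 2): MSX2 rose by 1.90 but stood at -0.05 with doublets kept, and the inner root sheath keratin gene KRT25 fell by 1.27 but stood at 0.20 with cells thinned to 1 number of UMIs.

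In keratinocyte-like cells at 6 months 6 of 8 antigen presentation genes rose, while the make-up of the class also differed: cluster 15, with KRT1 and KRT10 among its leading genes, held 165 of its 330 cells, against 41 of 233 and 53 of 405 at 6 weeks and 27 of 173 at 3 months. The median of the 8 was 1.51 against 0.08 between the 6-week replicates. BOLA rose by 2.52 to 4161 CPM, the proteasome gene PSMB9 by 2.08, and the peptide transporter genes TAP1 by 1.90 and TAP2 by 1.63. KRT25 rose by 3.32 to 562 CPM, while LGR5 fell by 1.61. PGGHG rose by 4.45, PSAT1 by 3.70, CLCA3 by 3.54 and WFDC18 by 3.49, and CCER2 rose by 6.95 but stood at -1.39 with Leiden resolution 2. The protease inhibitor gene CST6 fell by 5.87 from 4020 ± 889 CPM (SD, n = 2), S100A9 by 5.61, CRCT1 fell by 6.44, S100A8 fell by 3.79 and the desquamation protease gene KLK7 fell by 5.50. ATP6V1C2 had 2 counts at 6 months, a ratio of 133 (95% counting interval 36.4 to 1102). CXCL8 fell by 2.90, CXCL2 by 2.30 and MMP1 by 1.67, and of 7 wound epidermis genes 1 rose and 3 fell (median -1.01, or -0.42 without 6-week replicate 1). Of 12 chemokine and cytokine genes 3 rose and 5 fell (median -1.92), and the hair follicle list had a median of -0.74 (-2.04 with Leiden resolution 2), with 1 gene higher and 2 lower. The edgeR test called 1662 genes at 3 months (591 higher, 1071 lower) and 1381 at 6 months (732 higher, 649 lower) of 10014. Without robust moderation of the spread it called 442 and 289, and DESeq2 called 629 and 249. With Leiden resolution 2 it called 752 and 2722.

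In vascular endothelial-like cells, the chemokine genes CXCL5 and CXCL2 fell at 3 months and 5 of 10 basement membrane genes fell at 6 months. CXCL5 had 0 counts at 3 months against 530 ± 313 CPM (SD, n = 2) at 6 weeks, at least 759-fold lower against the floor of 3 counts (442-fold without 6-week replicate 2). CXCL2 fell by 7.16 from 8647 ± 5912 CPM (SD, n = 2) to 60.3 CPM, and the haem oxygenase gene HMOX1 fell by 7.12 from 1463 ± 530 CPM (SD, n = 2). CYP1A1, a target of the aryl hydrocarbon receptor, had 2 counts at 3 months, a ratio of 151 (95% counting interval 41.5 to 1257), and TUBA1C fell by 4.70. Of 18 chemokine and cytokine genes 2 rose and 4 fell at 3 months, and 2 rose and 0 fell at 6 months, with medians of -2.30 and -1.22 and a replicate difference of 1.02; the 6-month median was -1.07 with genes at 0 set at their bound, -1.89 without 6-week replicate 1 and -0.48 without replicate 2. CCL26, a chemokine of the eotaxin family, rose by 2.89 and 4.92 at 3 and 6 months, and CLCA3 by 4.78 and 5.61. RGS4 rose by 3.43, CLEC1A by 3.14 and APOD by 2.96 at 3 months. Of 14 cell cycle genes 5 fell at 3 months (median -1.32), among them PCNA by 1.60, and 0 passed at 6 months (median -0.94, or -0.43 without 6-week replicate 1). DLL4, a Notch ligand of vessel tips, rose by 1.97 at 3 months, while ESM1 fell by 3.14 and CXCR4 by 2.28, so that 3 of 13 angiogenic genes rose and 3 fell (median 0.16, or 0.25 and 0.065 without replicate 1 and 2 of 6 weeks); 1 fell at 6 months (median -0.56).

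At 6 months 5 of 10 basement membrane genes fell in vascular endothelial-like cells (8 adjusted over the list alone), with a median of -1.24 against -0.05 between replicates and -0.08 at 3 months, when 1 fell (0.039 without 6-week replicate 1). HSPG2, the perlecan gene, fell by 2.25, COL4A1 by 2.13, COL4A2 by 1.83 and the nidogen gene NID2 by 1.80. The lymphocyte chemokine gene CCL5 fell by 5.21, FABP4 by 3.20, PLAUR by 2.97, PNOC by 2.70 and LYVE1 by 2.66. BOLA-DQB, a class II histocompatibility gene, rose by 6.31 to 66.8 CPM, ACTA2 by 5.28 to 135 CPM and KRT14 by 5.15 to 283 CPM, beside the keratinocyte level given above. Of 12 antigen presentation genes 2 fell at 3 months, BOLA by 1.51 and B2M by 1.17, and 0 passed at 6 months, with medians of -0.41 and 0.63. The test called 1699 genes at 3 months and 172 at 6 months of 9770 in edgeR, but 0 and 0 without robust moderation (2586 and 983 at an unadjusted p under 0.05), 0 and 0 without a filter on low counts, and 483 and 68 in DESeq2. At 3 months 826 of the 1039 cells lay in cluster 8, which held 133, 107 and 31 cells of the other libraries.

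In mural-like cells CXCL8 was nearly without counts at 3 months, and 6 of 12 contractile genes rose at 6 months. CXCL8 had 3 counts at 3 months against 2843 ± 508 CPM (SD, n = 2) at 6 weeks, a ratio of 693 (95% counting interval 237 to 3362), and 3 counts at 6 months, a ratio of 77.5 (26.5 to 376). CXCR4 and C2CD4B had 1 count each at 3 months, ratios of 81.0 (14.4 to 3211) and 78.6 (14.0 to 3114). PLK2 fell by 4.17 and the pentraxin gene PTX3 fell by 4.11. MT1A, a metallothionein gene, rose by 3.54 and 4.58 at 3 and 6 months, and HTR2B by 3.10, NUMA1 by 3.03, MYOCD, a smooth muscle coactivator, by 2.99 and SETBP1 by 2.95 at 3 months. Of 12 contractile genes 4 rose at 3 months and 6 rose and 1 fell at 6 months, with medians of 0.08 and 1.26; the 3-month median was -0.41 with cells thinned to the smallest library and 0.13 and -0.081 without replicate 1 and 2 of 6 weeks. The smooth muscle myosin gene MYH11 rose by 2.00 and 2.23 and TAGLN by 1.05 and 2.28, and CNN1 rose by 3.42 and the desmin gene DES by 1.81 at 6 months.

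The 6-month mural-like class held 22 cells and 77322 UMIs. There 0 counts of FGF7 set it at least 14.2-fold lower, PRRX2 at least 8.60-fold, PTX3 at least 6.48-fold, CCK at least 5.72-fold and SERPINE2 at least 5.64-fold. Of 25 fibrillar matrix genes 11 fell (median -2.43, or -2.27 with genes at 0 set at their bound), against 3 higher and 3 lower at 3 months (median -0.25, or 0.16 without 6-week replicate 1 and -0.42 without replicate 2). The fibroblast marker gene DCN stood at 285 and 278 CPM in the mural-like cells of 6 weeks and at 24.3 CPM (2 counts) in the 22 cells of 6 months. COL1A1 stood at 957 and 662 CPM, then 85.2 CPM. Of 13 chemokine and cytokine genes 1 rose and 4 fell at 3 months (median -1.85) and 3 fell at 6 months (median -3.57, or -3.01 with bounds). The rises at 6 months rest on few counts. MKX rose by 6.37 (6 counts, against 0 and 2 at 6 weeks) and ASB2 by 4.98 (9 counts, against 5 and 4). PSMG3 rose by 4.69 (5 counts, against 3 and 3) and KRT14 by 5.09 (15 counts, against 4 and 10). The edgeR test called 1605 genes at 3 months (894 higher, 711 lower) and 296 at 6 months (110 higher, 186 lower) of 8494, and DESeq2 called 202 and 127.

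In T or NK-like cells at 3 months the interferon gamma gene fell and 9 of 17 dissociation response genes rose. IFNG fell by 3.94 from 858 ± 313 CPM (SD, n = 2) to 55.3 CPM, and CCL3 fell from 261 to 8.38 CPM. CCL20, which attracts CCR6-bearing cells, fell by 3.46, GNG4 by 4.15 and GBP2 by 3.96. Of 17 dissociation response genes 9 rose and 1 fell at 3 months (median 2.02) and 6 rose at 6 months (median 0.95), against 0.06 between replicates. DUSP1 rose by 3.88 and 2.64 and DNAJB1 by 3.14 and 3.72, HSPA6 by 3.75 and 5.59, and FOS by 3.50 and NR4A1 by 3.67 at 3 months. ZDBF2 rose by 4.34 at 3 months (2.75 without 6-week replicate 2), and PGGHG by 4.64, CTSD by 4.03, DNAJB4 by 3.82 and CALD1 from 9.68 to 158 CPM at 6 months. At 6 months CXCL2 fell by 5.81, GRO1 fell by 4.26 and CCL20 fell by 1.71. IL1R1 had 0 counts there, at least 6.00-fold lower, TWISTNB had 1 count, a ratio of 16.2 (2.85 to 646), and CDC27 had 2, a ratio of 11.7 (3.19 to 97.4). Of 10 chemokine and cytokine genes 2 rose and 2 fell at 3 months and 2 fell at 6 months, with medians of -0.13 and -0.81, the latter -0.22 with the gene at 0 set at its bound. Without 6-week replicate 1 the 3-month median was 0.042, and without replicate 2 the medians were -0.28 and -0.33.

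Of 12 fibrillar matrix genes 4 rose in T or NK-like cells at 3 months (median 2.67, against 0.68 between replicates), and 1 rose at 6 months (median -0.80, which was -1.37 without 6-week replicate 1 and 1.08 without replicate 2). COL1A1, a fibroblast gene, stood at 3.22 and 64.6 CPM in T or NK-like cells at 6 weeks, 419 CPM at 3 months and 31.5 CPM at 6 months, against 25761 CPM in the fibroblast-like cells of 3 months. The edgeR test called 899 genes at 3 months and 95 at 6 months of 6511 in this class, but 0 and 0 without robust moderation (1731 and 742 at an unadjusted p under 0.05), and 67 and 38 in DESeq2. At 3 months 374 of the 389 cells lay in cluster 7, which held 47, 146 and 38 cells of the other libraries.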

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

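The tests of dissociation genes, of free keratinocyte RNA and of stress genes in T or NK-like cells were chosen only after the result was seen; those of depth and of the best shared cluster were set down before their values, and the other clusters were added after. None of the patterns is called biological here, and time after grafting stays open for each, since 1 library at each later time cannot part it from animal or handling.

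Lower chemokine, cytokine and NF-kB genes in the fibroblast-like cells of both later times were weighed against depth, dissociation and cluster make-up. With every cell thinned to 1 number of UMIs the NF-kB median was -1.95 at 3 months and -1.31 at 6 months, beyond the 0.58 between the 6-week replicates. By the bound set for it, this counts against depth per cell. Thinning leaves the expected proportions within each cell as they were, however, and acts only by weighing cells alike and dropping shallow ones. The greater weight of deep cells is thus argued against, and other effects of depth stay open. A stronger dissociation response at 6 weeks is argued against at 6 months, where the dissociation list stood at 0.39; at 3 months it stood at -0.72, percentile 37.7 of random lists, which leaves it open. The sampling of other fibroblast clusters stays open, since clusters differ. In the clusters taken as best shared, the NF-kB median was 0.16 in cluster 16 at 3 months and -0.34 in cluster 3 at 6 months. Both lay within 0.58, the replicate difference of the whole class, which is no spread inside a cluster. Cluster 16 held 4 and 104 cells of the 6-week libraries, so its ratios are to replicate 2 alone. Clusters 6 and 13, held by both 6-week libraries, stood at 0.063 and -1.02 at 3 months. The median was -1.68 in cluster 4 at 3 months, and -1.09 in cluster 16 and -2.48 in cluster 4 at 6 months. Cluster 4 held 2032 of 2139 and 11222 of 12079 IL6 counts at 6 weeks but only 11 and 16 later cells, and clusters are themselves made from expression, so a change of state and a change of the cells sampled cannot be told apart.

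Keratin genes in the fibroblast-like, vascular endothelial-like and mural-like cells of 6 months could come from free keratinocyte RNA in that suspension. Of 24 other genes taken as keratinocyte-specific 37.5% were higher than in both 6-week libraries in all 3 classes (19 in fibroblast-like, 23 in vascular endothelial-like and 10 in mural-like cells), and their UMIs per cell lay within 2.59 times between classes. Among the 24, CCL20 is not specific: it stood at 992 and 1275 CPM in the T or NK-like cells of 6 weeks. In the vascular endothelial-like cells of 6 months it stood at 179 CPM. The bound set for the test, under 50%, counts against that source, but the mural-like cells held 33 UMIs over the 24 genes, too few to show a rise gene by gene. A minimum of UMIs per gene was therefore added after this value was seen, and with it the test leaves free RNA open. Summed over the 24 genes, mural-like cells held 1.50 UMIs per cell at 6 months against 0.353 and 0.349 at 6 weeks. Fibroblast-like cells held 3.07 against 1.79 and 1.60, and vascular endothelial-like cells 3.88 against 0.508 and 0.773. The T or NK-like cells, left out of that test, held 3.46 UMIs per cell at 6 months against 5.93 and 3.89 at 6 weeks, so their sum did not rise. CCL20 alone gave 308 of 433 and 1578 of 1628 of these UMIs at 6 weeks and 77 of 204 at 6 months, so that sum cannot decide. Their KRT14 stood at 431 and 9.70 CPM at 6 weeks and 324 CPM at 6 months. No biological explanation was tested.

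Immediate early and heat shock genes in the T or NK-like cells of 3 months were weighed against a stronger dissociation response of the whole suspension. In the fibroblast-like cells of the same suspension the dissociation list stood at -0.72, at percentile 37.7 of the random lists. The sign was the bound set for the test, and by it this counts against a response shared by all classes. Lists matched on expression fell about as much, so these cells showed neither a rise nor a fall particular to the list. The list lay over percentile 95 in the other 4 tested classes (2.02 in T or NK-like, 0.16 in keratinocyte-like, 0.16 in mural-like and -0.18 in vascular endothelial-like cells). Its median was thus below 0 in vascular endothelial-like cells too, and a response of cells other than fibroblasts stays open. 

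Cells outside the named classes drew attention because they passed the limit that a count of 0 allows. Cluster 0, led by VPREB1 and CCR7, held 4.91% of 6-week replicate 2, with 4, 210, 14 and 4 cells in the libraries in order of time. Cluster 11, with few UMIs per cell and IL1B and TYROBP among its leading genes, held 5.14% of 6-week replicate 1 (105, 98, 69 and 14 cells). Cluster 12, led by the hair keratin genes KRT35 and KRT85, held 6.07% of 6-week replicate 1 (124, 205, 25 and 10 cells). Cluster 21, with TYRP1 and PMEL among its leading genes, held 1.50% of the 6-month library (1, 0, 13 and 14 cells).

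Differences between the later times drew attention where list medians had opposite signs, and these differences were not tested. The fibrillar matrix list in T or NK-like cells stood at 2.67 at 3 months and -0.80 at 6 months, the latter 1.08 without 6-week replicate 2 and 0.43 with cells thinned to the smallest library. The interferon list in fibroblast-like cells stood at -0.29 and 0.90, the former 0.90 without 6-week replicate 1 and 0.060 with cells thinned to 1 number of UMIs, so neither pair had opposite signs in those settings. The hair follicle list in keratinocyte-like cells stood at 0.93 and -0.74, or 0.025 and -2.04 with Leiden resolution 2.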

How the results depend on the processing

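Of the alternatives below, leaving out the other later time, the test without robust moderation, and thinned UMIs for list medians were chosen only after the data were seen; the others were planned. The calls rest on 1 residual degree of freedom, the difference between the 6-week libraries, and each lone later library is assumed to vary like them. No paired analysis was possible because the labels do not tie libraries to animals and each later time has 1 library. Without a 6-week replicate the fit with time as a factor keeps no residual degree of freedom, so it gives values with no test; the line on log2 weeks keeps 1 and was tested. Animal, dissection day and time after grafting cannot be separated in these libraries. Depth differs by class: the mural-like class held 77322 UMIs in 22 cells at 6 months, and the keratinocyte-like class 728860 UMIs at 3 months and 5142736 at 6 months.

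Genes called by edgeR are given for 3 and 6 months in that order where the count moved by over 1.5 times; the cause was not tested except where stated. DESeq2 called 192 genes in fibroblast-like cells at 6 months, 629 and 249 in keratinocyte-like, 483 and 68 in vascular endothelial-like, 202 and 127 in mural-like, and 67 and 38 in T or NK-like cells. Size factors of the DESeq2 kind gave 1 and 12 in fibroblast-like cells, and at 6 months 473 in vascular endothelial-like and 155 in T or NK-like cells. Without a filter on low counts edgeR called 2207 and 1086 in fibroblast-like cells, and 0 and 0 in vascular endothelial-like cells (2325 and 975 at an unadjusted p under 0.05). With at least 50 counts in at least 2 libraries it called 373 in vascular endothelial-like cells at 6 months, 847 and 95 in mural-like cells, and 427 in T or NK-like cells at 3 months; fewer genes are tested under that filter. A line on log2 weeks in edgeR, which asks for a steady change, called 1 gene in fibroblast-like, 0 in keratinocyte-like (627 at an unadjusted p under 0.05), 3 in vascular endothelial-like, 0 in mural-like (677 at an unadjusted p under 0.05) and 2 in T or NK-like cells. In that line, without 1 of the 6-week replicates, 56 to 62, 22 to 26, 13 to 22, 4 to 10 and 3 to 6 genes were called in the same order of classes.

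With cells thinned to the smallest library, edgeR called 291 in fibroblast-like, 825 in keratinocyte-like and 280 in vascular endothelial-like cells at 6 months, 240 in mural-like cells at 3 months, and 480 and 178 in T or NK-like cells. With cells thinned to 1 number of UMIs it called 969 in fibroblast-like, 669 in vascular endothelial-like and 381 in T or NK-like cells at 3 months, 614 and 400 in keratinocyte-like cells, and 575 and 96 in mural-like cells. With Leiden resolution 2 it called 752 and 2722 in keratinocyte-like cells. With doublets kept it called 182 in fibroblast-like, 2822 in keratinocyte-like and 449 in vascular endothelial-like cells at 6 months, and 1377 and 223 in T or NK-like cells. With the other later time left out it called 335 and 64 in fibroblast-like cells, and 472 in vascular endothelial-like and 325 in T or NK-like cells at 6 months. Without robust moderation it called 442 and 289 in keratinocyte-like cells, 0 and 0 in vascular endothelial-like cells (2586 and 983 at an unadjusted p under 0.05) and 0 and 0 in T or NK-like cells (1731 and 742 at an unadjusted p under 0.05). With all cells of a library summed, 1503 and 817 genes were called against the 580 and 114 of fibroblast-like cells. The other counts of calls stayed within 1.5 times. Of the fibroblast-like values named as passing, 38 of 38 and 29 of 29 passed in DESeq2, 38 of 38 and 28 of 29 without robust moderation, 1 of 38 and 6 of 29 with size factors of the DESeq2 kind, and 0 of 38 and 1 of 29 in the line on log2 weeks.

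Shares of cells moved as follows, with 6 weeks, 3 months and 6 months in that order. Keratinocyte-like cells held 4.74%, 0.797% and 18.6% with Leiden resolution 2. At 6 weeks and 3 months they held 13.5% and 3.55% with Leiden resolution 0.5, 15.9% and 3.53% with doublets kept, and 16.4% and 3.67% with each library clustered by itself. With every deposited barcode they held 3.52% at 3 months and 39.1% at 6 months. Macrophage-like cells held 0%, 0% and 0% with Leiden resolution 0.5, with every deposited barcode and with doublets kept, and 0.347% at 3 months and 0% at 6 months with each library clustered by itself. Lymphatic endothelial-like cells held 0.240% of 6 weeks with every deposited barcode and 0% with each library clustered by itself, when mast-like cells held 0% of 6 months.

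Median log2 fold changes are given here, for 3 and 6 months, for the chemokine and NF-kB lists of fibroblast-like cells where they moved and for the medians counted as called that turned sign. Other printed medians that leaving out 1 library moved by over 1.5 times have that value beside them above. Chemokines and cytokines in fibroblast-like cells stood at -1.68 and -0.81 with cells thinned to the smallest library; without 1 of the 6-week replicates the range was -2.59 to -1.51 and -1.25 to -0.14. The NF-kB median at 6 months was -1.31 with cells thinned to 1 number of UMIs. The interferon median of fibroblast-like cells at 3 months was 0.060 with cells thinned to 1 number of UMIs, and -0.84 to 0.90 without 1 of the 6-week replicates. Their fibrillar matrix median at 3 months was -0.10 with size factors of the DESeq2 kind, -0.10 with cells thinned to the smallest library and -0.25 to 0.25 without 1 of the 6-week replicates. The contractile median of mural-like cells at 3 months was -0.41 with cells thinned to the smallest library and -0.081 to 0.13 without 1 of the 6-week replicates. The fibrillar matrix median of T or NK-like cells at 6 months was 0.43 with cells thinned to the smallest library and -1.37 to 1.08 without 1 of the 6-week replicates. Of 498 recomputed list medians, 9 turned sign where the median was counted as called.

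Among 4034 recomputed values of 296 named gene values, 54 turned sign, most of them with all cells summed (27), a setting that mixes classes by construction, and in the line on log2 weeks (18), which assumes a steady change. With all cells summed, at 3 months APOD stood at -0.15 (from vascular endothelial-like cells), CXCL12 at -0.15, MSX2 at -1.73, WFDC3 at -0.28 and WNT16 at -0.20 (keratinocyte-like), MT1A at -0.59 (mural-like), and DNAJB1 at -0.55 and IL1A at -2.68 (T or NK-like). At 6 months ACTA2 stood at -2.35 and BOLA-DMA at -0.031 (vascular endothelial-like), CALD1 at -1.72, CCL20 at 3.35, IL1A at -1.44 and TWISTNB at 0.012 (T or NK-like), and COL16A1 at 0.068, DES at -1.12, MKX at -0.48, MYH11 at -0.67 and TAGLN at -0.056 (mural-like). In the same setting EN1 stood at -0.42, PTN at 0.88, SLC2A1 at 0.48, TFAP2A at 1.64 and TNFAIP3 at 0.20 (fibroblast-like), and LGR5 at 0.20, MMP1 at 0.38 and S100A7 at 1.09 (keratinocyte-like).

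In the line on log2 weeks, against 3 months, B2M stood at 0.13, BOLA at 0.71, C4A at 0.21, IFI6 at 0.41, IRF7 at 0.38, SERPING1 at 0.26, TBX15 at -0.10 and TRPS1 at -0.31 (fibroblast-like), BOLA at 1.07, CXCL12 at -0.81 and KRT25 at 1.45 (keratinocyte-like), and B2M at 0.22, BOLA at 0.28 and CCL20 at 0.52 (vascular endothelial-like). Against 6 months LGR5 stood at 0.59 (keratinocyte-like), LOXL3 at 0.42 (mural-like), and COL12A1 at 0.58 and COL5A2 at 1.31 (T or NK-like). In keratinocyte-like cells WNT16 at 3 months stood at -1.48 and CCER2 at 6 months at -1.39 with Leiden resolution 2, MSX2 at 3 months at -0.050 and CCER2 at 6 months at -1.15 with doublets kept, and KRT25 at 3 months at 0.20 with cells thinned to 1 number of UMIs. In fibroblast-like cells, without 1 of the 6-week replicates, TFAP2A stood at -1.82 to 0.041 and BAMBI at -1.65 to 0.047 at 6 months, and C4A at -2.12 to 0.86 and CCL20 at -7.34 to 4.18 at 3 months. No named gene turned under the 7 other settings. These took named values off the threshold: 39 in DESeq2, 31 without a filter, 5 with at least 50 counts in at least 2 libraries, 60 with size factors of the DESeq2 kind, 32 with cells thinned to the smallest library, 13 with the other later time left out and 66 without robust moderation.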

Other observations

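The values below were chosen after they were seen, and no test was run on them. Macrophage-like cells, 49 and 56 at 6 weeks, 41 at 3 months and 16 at 6 months, were too few in the last library for a test. IL1B, an inflammatory cytokine gene, stood at 8620 and 5402 CPM at 6 weeks, 3325 CPM at 3 months and 49.7 CPM at 6 months, and CCL3 at 7183, 6184, 1182 and 155 CPM in that order. The mannose receptor gene MRC1 stood at 45.5 and 150 CPM at 6 weeks and 691 CPM at 3 months, SELENOP at 182, 836 and 2485 CPM, and the complement gene C1QA at 83.8, 465 and 877 CPM, while VSIG4 stood at 0, 14.6 and 13.5 CPM. The 16 cells of 6 months held 0 counts of MRC1, 3 of C1QA and 1 of CCL4 in 160876 UMIs, so their class is less sure than the cluster name says. CXCL8 stood at 40575, 32243, 14265 and 11537 CPM.

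In the mast-like cells CCL2, a monocyte chemokine gene, stood at 1952 and 1427 CPM at 6 weeks and 165 CPM at 3 months, and LIF, a cytokine gene, at 16.0, 8.09 and 103 CPM. GATA2, a mast cell regulator, stood at 1900, 2066 and 4123 CPM, and the marker gene CPA3 at 1016, 1229 and 758 CPM. The 3 mast-like cells of 6 months held 20 counts of CCL2 in 8640 UMIs, or 2315 CPM, so its low level at 3 months was not seen there. The lymphatic endothelial-like cells of 6 weeks were 4 and 5 in number. CCL21, the chemokine that guides cells into lymphatics, stood at 16710 CPM in the 20 cells of 3 months and 16761 CPM in the 45 cells of 6 months. The other markers of the class all stood lower at 6 than at 3 months. In that order of 3 and 6 months, RELN stood at 1047 and 71.5 CPM, MMRN1 at 8854 and 2031 CPM and PROX1 at 2226 and 715 CPM. LYVE1 stood at 1768 and 247 CPM, FLT4 at 753 and 133 CPM and PDPN at 638 and 286 CPM.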
